A study of Mus musculus with 2 samples.

How the data were processed

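H3K4me1 ChIP-seq was done on heart tissue of B6NCrl mouse embryos of mixed sex at embryonic day 13.5. Per the labels, there were 2 biological replicates, each with 1 library, from the ENCODE project, and the size range given is 300 to 500 bp. Nothing in the labels says how many embryos entered a pool.

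The deposited files were 4 peak lists in narrowPeak form on mm10, made by the authors from filtered alignments. Per the text deposited with the lists, replicate 1 and the pooled reads were each compared with 2 control files and replicate 2 with 1 of them, so the replicates differ in their controls. The replicated list was made from the 2 replicate lists and the pooled list. The aligner, the peak caller, the threshold and the rule for the replicated list are not given in the sources used here. Each peak has a deposited score of 10 to 1000, scaled by the authors within each list, a deposited signal value above 1 whose scale is not given in the sources used here, and the authors' -log10 p and -log10 q against control. The summit of each peak is the authors' offset. These values per peak are the authors' own and were used to rank, filter and describe peaks within a list, and for the correlation between replicates.

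The design written before the data were examined had called the signal a fold enrichment. Because its scale is not given, it is called a signal value here. The depth of the libraries is unknown, so no value is corrected for depth, and a longer list can come from more reads. The chromosome names and lengths of GRCm38 (the assembly behind mm10) held every peak. Genes were taken from GENCODE M21, with 21911 protein-coding genes after 1 entry was kept per symbol. The TSS of a gene was that of its principal protein-coding transcript. The few peaks on unplaced sequence (1 to 3 per list) were left out.

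Overlap required at least 1 bp. Correlations used peaks that overlapped one to one, the log2 of the signal value, and no p-value, since peaks are not replicates. Ranks were by -log10 p, which the score follows. Shuffles placed the same intervals at random on the same chromosome outside runs of unknown bases, 100 times. The summit of a peak was assigned in the order within 1 kb of a TSS, 5' UTR, coding exon, 3' UTR, intron and between genes. A promoter was CpG-rich with an observed over expected CpG ratio of at least 0.6 and a GC share of at least 0.5 within 500 bp of the TSS.

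Coverage was the percent of bp within 50 kb either side of the TSS that lies in peaks. All 19 gene lists, the olfactory and vomeronasal receptor genes among them by symbol prefix, were fixed before the data were examined, as were the comparisons and the alternatives not named here as later. Each list's median was set among 10000 random lists of the same size, matched on 5 bins of gene length, 4 bins of protein-coding TSSs within 50 kb and promoter class, and called high in the top 2.5% and low in the bottom 2.5%. A class with fewer than 5 other genes was matched on promoter class alone. The receptor list and the genes of X were set among 1000 lists and not the 10000 planned. These percentiles describe these libraries and are not p-values, and neighbouring genes of a list share windows. The main values come from the replicated list. Replicates are given as mean ± SD (n = 2) of values from their own lists, which are lower than those of the replicated list, whose peaks come from the pooled reads. Domains were peaks joined over gaps of at most 1 kb. Motif windows reached 250 bp either side of the summit, and background windows of the same size on the same chromosomes lay outside all peaks and over 2.5 kb from a protein-coding TSS, matched on GC in 2% bins and on the number of CpGs. A window counted with at least 1 match on either strand, and the reversed motif string served as control. Exact Clopper-Pearson intervals at 95% cover counting error only. In the alternative with flanking background, 54.0% of windows found a match of the same composition. The profile of motif matches by distance from the summit was added after the data were seen.

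Genes named in the text follow a rule fixed beforehand: a panel of 26 heart and contrast genes, the 2 most and 2 least covered members of each list, the 15 genes with most coverage at least 100 kb apart, the genes of the 15 longest domains and of the 10 peaks with the highest score. Alternatives were each replicate alone, a -log10 q of at least 5, the pooled list, other overlap rules, windows, gaps, gene types, matching and backgrounds. Peaks found in both replicates and windows with few repeats were added after the data were seen. A single value counted as unmoved when it moved by less than 1 SD between the replicates or stayed in its 95% interval, and a count when it stayed within 1.5 times.

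On simulated data the overlap step found the share of shifted copies exactly (59.6% of 20000 intervals). With 21911 genes and shuffled values, 1.5% of 400 unchanged lists of 20 genes came into the top 2.5%, and 88.8% of lists raised by 10 percentage points did. A motif planted in 20% of 5000 windows gave a ratio of 14.6 where 14.1 was simulated. The shuffled values lacked the shared windows of neighbouring genes, and the motif was planted in random sequence without matched background. These checks therefore cover the calculations and not the error rate on the real data. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.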

Results

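H3K4me1, the single methyl group on lysine 4 of histone H3 that marks enhancers and the borders of active promoters, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse heart at embryonic day 13.5. At this stage the chambers have formed and the valves, coronary vessels and epicardium are still developing. The tissue came from healthy embryos of strain B6NCrl, males and females pooled, and the labels name 2 biological replicates of 1 group. The deposited lists held 245220 peaks for replicate 1, 230308 for replicate 2, 259775 for the pooled reads of both and 184395 in the replicated list. Replicated peaks had a median width of 669 bp and covered 6.75% of chromosomes 1 to 19 and X, and the lists of the separate replicates covered 6.29% and 5.76%. Read totals are not in the files used here, so the sequencing depth behind each list is unknown, and with 1 group every value below describes this tissue without a test against another.

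The first comparison the design implies is between the replicates. The strongest H3K4me1 sites of the embryonic heart were found in both: of the strongest 10% of peaks, 99.96% in replicate 1 and 99.99% in replicate 2 overlapped a peak of the other. In the weakest 10% the shares were 43.6% and 59.2%. Weak peaks were also narrower, with a median width of 241 bp in the weakest bin of replicate 1 against 1621 bp in the strongest, and overlap by 1 bp depends on width. At shuffled positions the same bins of replicate 1 fell from 16.99% to 8.61%. Over all peaks, 74.4% of replicate 1 peaks (exact binomial 95% confidence interval 74.2 to 74.5%) overlapped replicate 2, and 82.1% of replicate 2 peaks (81.9 to 82.2%) overlapped replicate 1. The same intervals at shuffled positions of the same chromosomes overlapped in 10.8% and 11.5%. When 50% of each peak had to be shared, the shares fell to 49.3% and 52.5%.

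**Figure D1:**
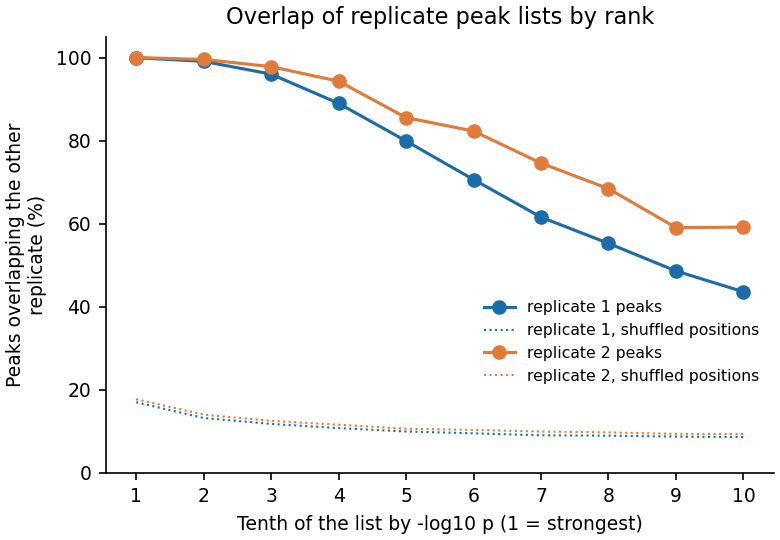
Percent of peaks overlapping the other replicate by at least 1 bp (vertical axis) in bins of 10% of each list from the strongest to the weakest by -log10 p (horizontal axis), with dotted lines for the mean of 100 shuffles of the same bins. Overlap falls from 99.96% to 43.6% in replicate 1 and from 99.99% to 59.2% in replicate 2, and every bin lies above its shuffled mean, which falls from 16.99% to 8.61% in replicate 1 and from 17.7% to 9.36% in replicate 2 as peaks become narrower.

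Peak strength in the replicates was correlated across 114015 pairs of peaks that overlapped one to one. Pearson's r of the authors' signal value on the log2 scale was 0.643 and Spearman's rho 0.588, across peaks, which are not independent replicates. For -log10 p, r was 0.773. Covered percent around genes was closer still: over 21911 protein-coding genes, the percent of bp covered within 50 kb of the transcription start site (TSS) had r = 0.995 between the replicates, and the median SD between them was 0.484 percentage points (n = 2).

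The replicated list was a subset of the pooled list, with 71.0% of its peaks. These were the stronger ones, with a median signal value of 3.39 against 2.36 in the pooled peaks left out, and the authors' -log10 q reached 5 in 79.1% against 9.02%. Every pooled peak that shared at least 50% of its own or of the other peak's length with a peak in each replicate was in the list (154635 peaks). Another part of the list did not meet that: 28776 peaks, 15.6%, did not overlap a peak of both replicates, and these were narrow, with a median of 341 bp against 778 bp for the rest.

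Most H3K4me1 lay in the introns of protein-coding genes and between genes, away from promoters. Of the replicated summits, 54.6% fell in introns, 1.46 times the share at shuffled positions (37.5%), and 32.5% lay between genes, 0.563 times the shuffled share (57.8%). Only 9.41% lay within 1 kb of a protein-coding TSS, but this was 4.33 times the shuffled 2.17%. The replicates alone gave 8.16% and 8.57%. In all, 83.4% of summits were over 2.5 kb from a protein-coding TSS, at a median distance of 24700 bp for all summits. Coding exons held 1.87% of summits and 3' UTRs 1.47%, against 1.24% and 1.27% at shuffled positions.

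At CpG-rich promoters, which belong mostly to broadly expressed and developmental genes, H3K4me1 flanked the start site and was scarce on it. Of 10100 such promoters, 95.3% had a replicated summit within 2 kb, while the TSS base itself lay inside a peak at 9.69%. Summits were densest in the bins centred 550 bp upstream and 950 bp downstream. The density within 200 bp of the TSS was 0.213 times that at 0.5 to 2 kb, with 0.231 in replicate 1 and 0.230 in replicate 2. CpG-poor promoters, typical of tissue-restricted genes, differed. Of 11811 such promoters, 43.3% had a summit within 2 kb, the TSS base was covered at 19.5%, and the centre was 1.61 times the flank (1.52 and 1.46 in the replicates). Without olfactory and vomeronasal receptor genes, 52.5% of 9460 CpG-poor promoters on autosomes and 17.9% of 705 on X had a summit within 2 kb. Downstream summits outnumbered upstream ones 1.36 times at CpG-rich and 1.55 times at CpG-poor promoters.

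**Figure D2:**
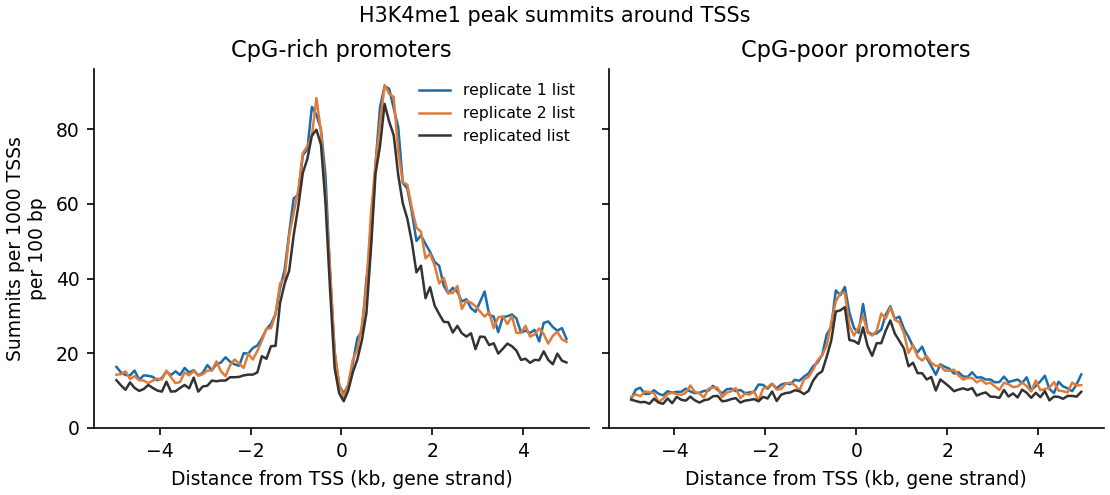
Summits per 1000 TSSs in 100 bp bins (vertical axis) by distance from the TSS along the gene strand in kb (horizontal axis), for CpG-rich (left) and CpG-poor promoters (right), with a line each for the replicate 1, replicate 2 and replicated lists. CpG-rich promoters show a dip at the TSS between maxima 550 bp upstream and 950 bp downstream in the replicated list, and CpG-poor promoters have a centre 1.61 times the flank.

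Around genes of the heart's own cell types, H3K4me1 covered far more of the chromosome than around matched genes. Of 9 heart lists fixed beforehand, 8 had a median covered percent within 50 kb of the TSS in the top 2.5% of 10000 random lists matched on gene length, neighbouring TSSs and promoter class. All 8 stood there with either replicate's own peaks too. The cardiac transcription factors had 31.4%, against 7.87% for matched lists, and sarcomere genes 29.8% against 6.17%. The order of this pair turned with each replicate's own peaks, where sarcomere genes had 27.2% and 26.97% and the transcription factors 27.1% and 26.2%. Next came calcium handling and ion channels with 25.1% against 6.90%, and endothelial and endocardial genes with 23.7% against 8.50%. The median over all protein-coding genes was 8.49%. Matched lists could hold olfactory and vomeronasal receptor genes and genes of X, and whether these lowered the matched medians was not tested.

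Among the 25 cardiac transcription factors, 16 were in the top 25% of all genes and none in the bottom 25%. Tead1, a partner of the Hippo pathway's coactivators, had 59.9% of its window covered, and the replicates' own peaks gave 55.7% ± 1.27 (SD, n = 2). Gata4, a zinc finger factor needed for heart formation, had 57.5% (54.0% ± 0.0389 in the replicates), with its TSS at chromosome 14 position 63245248. Its relative Gata6 had 37.5% and Tbx5, mutated in Holt-Oram syndrome, 40.0%. Nkx2-5, an early cardiac homeobox factor, had 32.7%, Tbx20 31.5%, Hand2 31.3% and Hand1 22.2%. Mef2c, a MADS box factor of muscle, was near the middle of all genes with 11.3%. The lowest were Hey2, a Notch target of the ventricle, with 9.08%, and Isl1, a second heart field factor, with 3.09% (2.39% ± 0.0085 in the replicates).

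Of the 27 sarcomere genes, 23 were in the top 25%. Tnni1, the slow skeletal troponin I that the embryonic heart uses, had 61.2% and its neighbour Tnnt2, cardiac troponin T, 54.6% (50.05% ± 1.03 in the replicates). Their windows overlap on chromosome 1. The myosin heavy chain pair Myh6 and Myh7, side by side on chromosome 14, had 41.1% and 33.7%. Ttn, encoding titin, had 16.04% and Actc1, cardiac actin, 9.47%. Smpx, a small muscle protein on chromosome X, had the lowest value, 2.19%. Of the calcium handling and channel genes, 13 of 20 were in the top 25%, led by Ryr2, the calcium release channel of the sarcoplasmic reticulum, with 55.5%, and Jph2, which ties that membrane to the cell surface, with 50.9%. Hcn1 (2.63%) and Kcnd2 (0.717%) were lowest. The chamber and natriuretic list of 12 genes stood at 20.0% against 5.99% for matched lists, from Itga6 (35.8%) and Popdc2 (32.1%) to Slit3 (9.67%) and Cited1 (1.06%). The natriuretic peptide genes Nppa and Nppb, neighbours on chromosome 4, had 18.4% and 17.9%.

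The vascular, signalling and connective tissue lists were raised to different degrees. Of 25 endothelial and endocardial genes, 14 were in the top 25%, with Lyl1, a blood and vessel bHLH factor, at 62.0% and Eng, a TGF-beta coreceptor, at 48.9%. Cdh5, encoding VE-cadherin, had 8.31%, Tal1 12.3%, and Sox17 (4.36%) and Erg (1.57%) were lowest. The 24 cardiac signalling genes had a median of 19.7% against 8.57%. The inhibitory SMADs led with Smad6 at 70.0% and Smad7 at 53.2%, while Wnt2 (4.12%) and Fgf16 (3.46%) were lowest. Smooth muscle and pericyte genes stood at 14.97% against 5.31%, from Smtn (33.9%) and Notch3 (18.9%) to Myh11 (6.44%) and Rgs5 (2.65%). Mesenchyme, valve and fibroblast genes stood at 11.4% against 5.32%, from Tgfb2 (41.6%) and Snai1 (32.7%) to Postn (3.50%) and Col3a1 (1.26%). These last lists lay at percentiles 98.2 and 98.7. With a window of 100 kb they fell to 92.0 and 84.5, and against lists that were not matched to 92.1 and 82.2, so both left the called range, and by number of peaks the mesenchyme list did so too, at 95.7.

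The epicardial list was the heart list that did not stand apart. Its median of 8.27% lay at percentile 63.5, against a matched median of 7.06%, with 65.2 and 74.8 for the replicates' own peaks. Wt1, a zinc finger factor of the epicardium, had 21.5% and Msln 18.0%. Tbx18 had 8.27% and Tcf21 7.997%, and Bnc1 (4.36%) and Gpm6a (0.472%) were lowest.

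**Figure D3:**
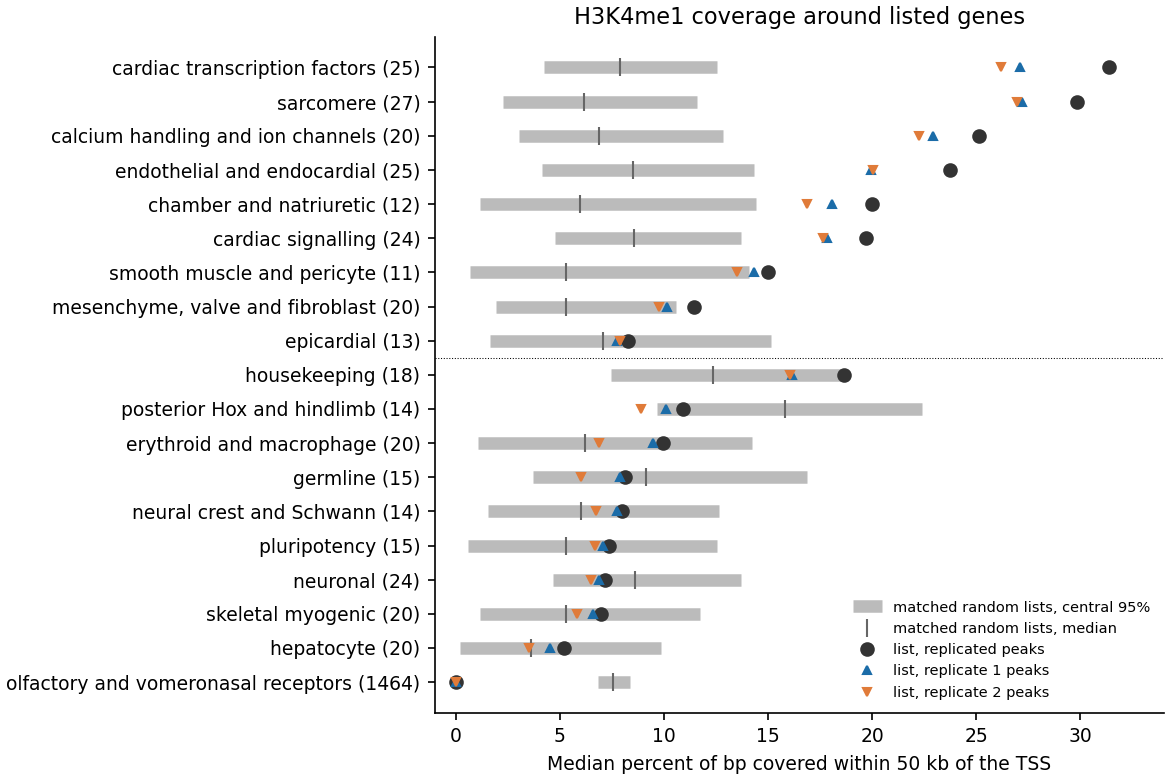
Median percent of bp covered within 50 kb of the TSS (horizontal axis) for each gene list (vertical axis, number of genes in parentheses), heart lists above the dotted line. Circles are the replicated peaks, triangles each replicate's own peaks, and grey bars the central 95% of random lists matched for the replicated peaks; cardiac transcription factors reach 31.4% against a matched median of 7.87%, and receptor genes lie at 0%.

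Genes of other tissues were mostly covered like matched genes within 50 kb. The 20 hepatocyte genes had a median of 5.196% (percentile 70.2), the 24 neuronal genes 7.17% (25.7), the 20 skeletal myogenic genes 6.97% (72.1), the 15 pluripotency genes 7.35% (71.7), the 15 germline genes 8.12% (37.4) and the 14 posterior Hox and hindlimb genes 10.9% (6.54). Other windows changed the calls of 3 of these lists: germline genes were low within 10 kb (percentile 0.09) and over gene bodies (0.1), posterior Hox genes were low within 100 kb (2.0), and skeletal genes were high over gene bodies (97.9). Lists of cells that a dissected heart may carry also lay within the matched range, with 9.93% (83.4) for erythroid and macrophage genes and 7.99% (73.7) for neural crest and Schwann cell genes. Alb, encoding serum albumin, had 1.18%, Neurod1 3.18%, Myod1 3.97% and Nanog 7.08%. Housekeeping genes stood at 18.6%, percentile 97.7. They left the called range with the peaks of replicate 1 alone (94.0), within 100 kb (92.2) and over gene bodies (97.4), among other alternatives. The 1464 olfactory and vomeronasal receptor genes, which are expressed in the nose, were the lowest, with a median of 0%, 1174 without any covered bp and percentile 0 among 1000 matched lists.

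Single members of these lists ranged widely. Tnnt3 (59.7%) and Tnni2 (40.5%), fast skeletal troponins in a cluster on chromosome 7, led the skeletal list, and Myh8 (1.15%) and Eya1 (1.05%) closed it. In the neuronal list, Neurod2 had 35.4% and Slc17a7 26.7%, against 1.39% for Syt1 and 0% for Slc17a6. Among hepatocyte genes the highest were Apoa2 (28.0%) and Apoa1 (17.0%), with Cyp2e1 and Serpina1a at 0%. The blood list ran from Nfe2 (34.2%) and Spi1 (27.9%) to Adgre1 (1.23%) and Gata1 (0.925%), and the neural crest list from Dbh (36.7%) and Mpz (24.2%) to Tfap2b (0.422%) and Plp1 (0%). Lin28a (15.4%), Tfcp2l1 (12.97%), Dppa4 (1.29%) and Zfp42 (0%) bounded the pluripotency list, and Spo11 (32.9%), Prm1 (28.9%), Sycp1 (0.94%) and Zpbp (0%) the germline list. In the posterior list Tbx4 (16.1%) and Hoxa10 (15.7%) were highest and Hoxc12 (5.42%) and Hoxc13 (4.22%) lowest. Rplp0 (40.2%) and Eef2 (37.2%) led the housekeeping list, and Hprt (4.70%) and Pgk1 (2.19%) closed it. A window of 50 kb takes in neighbouring genes, so a value belongs to the region and not to the named gene alone. Of the 36 lowest members, 7 were on chromosome X, and none of the 36 highest.

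At the fixed panel of genes, the strongest replicated peak within 50 kb was found in both replicates for each gene except Alb, whose peak overlapped a peak of replicate 1 only. For Gata4 it lay upstream between genes, 38.7 kb from the TSS, at chromosome 14 positions 63282828 to 63285032, with a signal value of 8.36. The Tnnt2 peak, with its summit in an intron of the gene, spanned chromosome 1 positions 135839025 to 135849229. It was 10205 bp wide with a signal value of 8.71. Myh6 and Myh7 shared theirs, 8.21 kb upstream of Myh7 at chromosome 14 positions 55001919 to 55005152, with 9.06. For Ryr2 the summit was intronic, 33.97 kb inside the gene, and the peak had 6.48. At Alb it was 210 bp wide with 2.79.

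**Figure D4:**
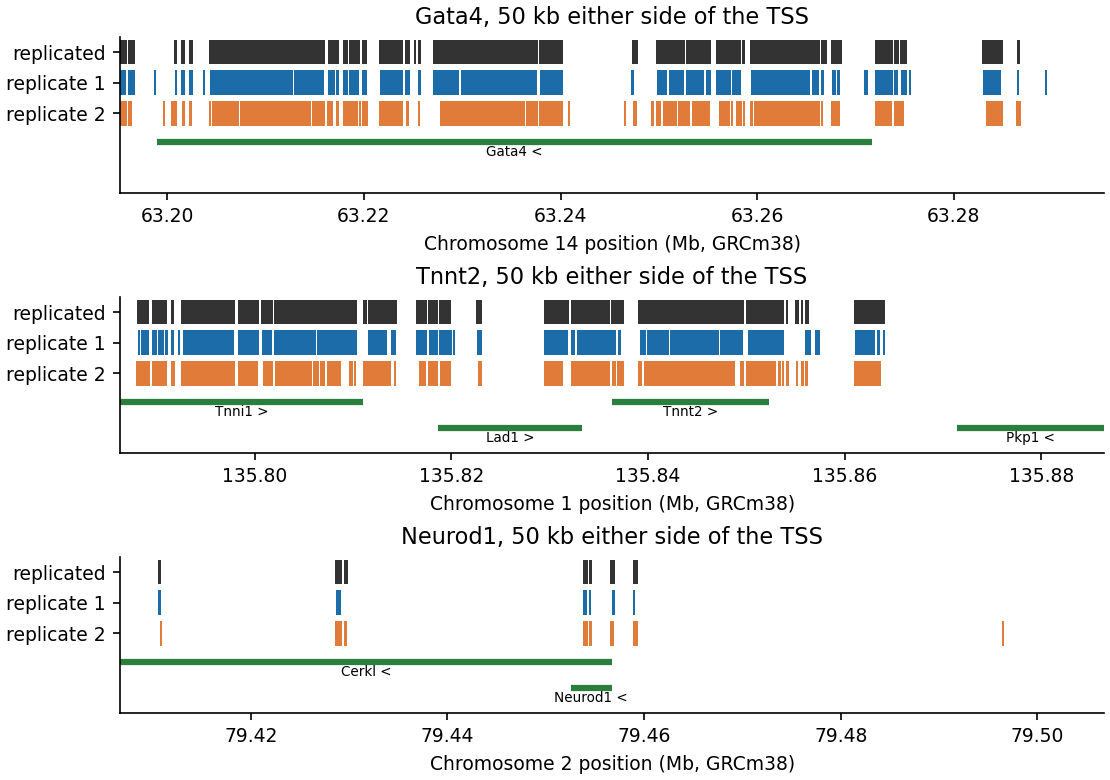
Peaks of the replicated list and of each replicate (rows) within 50 kb either side of the TSS of Gata4, Tnnt2 and Neurod1, by chromosome position in Mb on GRCm38 (horizontal axis), with protein-coding genes as green bars and arrows for their strand. Replicated peaks cover 57.5% of the Gata4 window, 54.6% of the Tnnt2 window and 3.18% of the Neurod1 window.

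Over all protein-coding genes, the regions with the most H3K4me1 lay around genes of varied function. Lrrfip1 on chromosome 1 had 83.9% of its window covered (78.2% ± 3.94 in the replicates, SD, n = 2). Col4a1, a collagen of basement membranes, had 76.3%, Gse1 72.8%, and Igf2r, the receptor that clears insulin-like growth factor 2, 72.4%. Smad6 (70.0%) and Smad3 (63.2%), an inhibitor and a mediator of TGF-beta family signalling, were both among these 15. So were Mical3 (70.9%) and Mical2 (68.7%), enzymes that oxidise actin filaments, Dab2ip (69.7%), Zmiz1 (67.0%), Synpo (65.8%), Iqsec1 (64.1%), Sptbn1, a spectrin (64.0%), Rbms1 (63.9%) and Lad1 (62.9%), which lies between Tnni1 and Tnnt2.

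Joining peaks at most 1 kb apart gave 112772 domains with a median length of 1.05 kb. The longest, 93.5 kb at chromosome 7 positions 112227089 to 112320607, lay inside Mical2, and peaks filled 94.7% of it (90.0% and 87.6% in the replicates). Shb (78.5 kb), Sipa1l2 (76.9 kb), Lrrfip1 (69.7 kb), Mical3 (67.0 kb), Zmiz1 (66.9 kb) and Dab2ip (63.2 kb) followed, all overlapping the gene named. The other domains of the 15 longest, from 59.4 to 55.1 kb, overlapped Tns1, Synpo, Vgll4, Creb3l2, Ssbp3, Gab1, Etv6 and Ncor2. Of the 500 longest domains, 5.80% came within 50 kb of a gene of the heart lists, 5.88 times the 0.986% at shuffled positions. For any protein-coding gene, 402 domains did so against 239 when shuffled. The shuffles were not matched on nearness to genes or on gene length, so the excess near heart genes includes any such general effect. Domains near the same gene were counted separately. By list, 7 of the 500 were near sarcomere genes (0.77 when shuffled), 6 near calcium handling and channel genes (0.3), and 5 each near cardiac transcription factors (0.67), endothelial (0.81) and signalling genes (0.45). Chamber and mesenchyme genes had 1 each, and epicardial and smooth muscle genes 0. Of the other lists, germline genes had 2 (0.18), skeletal, neural crest and housekeeping genes 1 each, and receptor genes 0 against 11.9 when shuffled. The remaining lists had 0, where the shuffled means were 0.55 or lower, too few to show a lack. The widest gap tried lowered the excess to 3.16 times.

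The 10 peaks with the highest score, the authors' scaling of peak strength within the list, had their summits in introns except that of Per1, a circadian clock gene, 687 bp from a TSS. The strongest was in Stk24, a kinase gene, at chromosome 14 positions 121364115 to 121370935, with a signal value of 12.8. Hdac5, a histone deacetylase gene that restrains MEF2 (chromosome 11 positions 102219011 to 102221503, signal value 12.01), Phc2, Fmnl3, Fam129b, Gse1, Igf1r, Ptp4a3 and Arhgef7 held the others. Their signal values were 11.1 to 12.4. The Gse1 peak also lies in the overlapping gene model Gm20388.

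Chromosome X carried few peaks. It held 11.8 replicated peaks per Mb, against a median of 74.3 over the autosomes and a range from 59.7 on chromosome 14 to 102 on chromosome 11. The ratio to the autosomal median was 0.159, with 0.157 in replicate 1 and 0.168 in replicate 2. Covered bp were lower still, 0.778% of X against a median of 7.16%. Protein-coding genes per Mb on X were 0.71 and CpG-rich promoters 0.341 of the autosomal medians. On X, 64.5% of 234 CpG-rich promoters had a summit within 2 kb (exact 95% interval 58.0 to 70.7%), against 96.1% of 9866 on autosomes. No list had a peak on chromosome Y.

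Distal H3K4me1 sites, over 2.5 kb from a protein-coding TSS, carried binding motifs of heart transcription factors more often than background sequence of the same GC and CpG content. Within 250 bp of the summit, MEF2 sites stood in 9.38% of 153427 windows against 6.02% of background windows, a ratio of 1.56. GATA sites stood in 32.1% against 21.8% (1.47), ETS sites, bound by endothelial factors among others, in 7.48% against 4.999% (1.495), and the E-box of TCF21 and MYOD in 29.8% against 23.1% (1.29). NKX2 (1.22), MEIS (1.22) and TEAD (1.15) were higher as well, each with exact binomial 95% intervals apart, which cover counting error only. Much of the excess of MEIS and NKX2 was shared by their reversed strings, with ratios of 1.16 and 1.12. TBX (1.03) and SRF (1.03) had overlapping intervals, but those of SRF were apart against flanking background (1.12) and in windows with few repeats (1.16). The HAND and TWIST E-box (0.981) was slightly rarer than in background, more frequent within 100 bp (1.03), and had overlapping intervals over whole peaks (0.996) and against flanking background (0.992). Each of the 10 heart motifs did better than its own reversed string, by a median of 1.22 times (1.24 and 1.23 in the replicates). For the 6 motifs of other tissues the median was 1.03, but RFX reached 1.66, above each heart motif, and POU 1.24. Some of these reversed strings were rare. That of RFX had 32 matches within 100 bp of distal summits and 47 at 100 to 250 bp, and that of HNF1 13 and 39. Their ratios, and the median they enter, are therefore imprecise. The gap between the kinds was not kept in every window: within 100 bp the medians were 1.28 for heart and 1.26 for other motifs, and over whole peaks 1.18 and 1.19. TBX did not exceed its reversed string against flanking background (0.997) or in windows with few repeats (0.956).

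Motifs of other tissues were split. SOX (0.795), POU (0.803) and CRX and OTX sites (0.895) were rarer at summits than in background, HNF4 (1.03) and HNF1 (1.11) had overlapping intervals, and RFX sites were more frequent (1.36). Against flanking background RFX (1.11), SOX (1.01) and POU (0.969) had overlapping intervals. AP-1 sites had a ratio of 1.31, which was 1.17 times that of their reversed string. CTCF sites, which anchor chromatin loops, had a ratio of 2.17 within 250 bp of the summit, in 0.696% of windows against 0.321%. Over whole peaks, which were 841 bp long on average, the direction turned, with 0.460% against 0.620% (0.743). The windows reach past the ends of narrow peaks, and the lower quartile of replicated peak width was 415 bp. The CTCF excess therefore holds for windows around summits and not for the peaks themselves. How many window matches lay outside the peaks was not counted. The reversed CTCF string was rare, in 0.0176% of windows against 0.0091% (1.93). Its ratio was 0.844 in replicate 1 and 1.04 in replicate 2, so that control says little for CTCF. Background windows held more repeat sequence, 32.4% soft-masked bases against 14.5%. In windows with at most 10% on each side, an alternative added after the data were seen, SOX, POU and CRX and OTX sites moved to 1.03, 1.04 and 1.01, RFX to 1.105, HNF4 to 0.866 and HNF1 to 0.952.

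CTCF sites were scarcer under the summit than beside it. Their density within 100 bp of distal summits was 0.206 times that at 100 to 250 bp (exact 95% interval 0.171 to 0.247), with 0.291 in replicate 1 and 0.260 in replicate 2. It rose from 3.51 matches per Mb in the first 50 bp to 29.3 per Mb at 200 to 250 bp. Within 100 bp of the summit, CTCF windows were rarer than background, with a ratio of 0.433. The TCF21 and MYOD E-box had the opposite profile (1.34, reversed string 1.04). ETS sites did too (1.18), but so did their reversed string (1.17). GATA sites were nearly level (0.951), while their reversed string was scarcer near the summit (0.715). MEF2 sites were also scarcer near the summit (0.517), as was their reversed string (0.413), a pair of AT-rich strings.

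**Figure D5:**
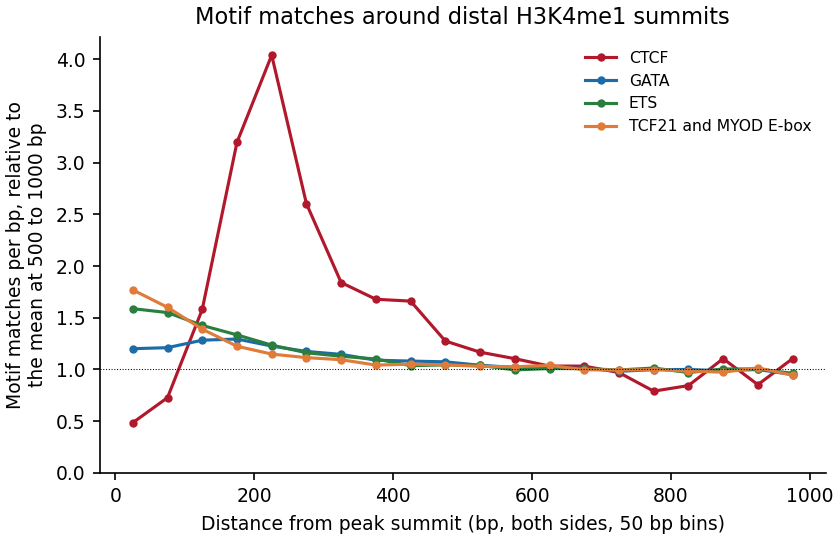
Motif matches per bp around distal summits of replicated peaks (vertical axis, relative to the mean at 500 to 1000 bp) by distance from the summit in 50 bp bins, both sides together (horizontal axis), with a line for each of 4 motifs. CTCF matches rise from 3.51 per Mb at the summit to 29.3 per Mb at 200 to 250 bp, while ETS and E-box matches are densest at the summit.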

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

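Peaks found in both replicates and windows with few repeats were chosen after seeing the data; the other alternatives were fixed beforehand. No value without a replicate exists for the 3 results that compare the replicates. Except where a cause is named, the cause was not tested.

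The number of heart lists in the top 2.5% of matched lists, 8, stayed from 6 to 8 in all 10 alternatives. Of 190 list values in those alternatives, 175 kept their side of the threshold, 11 fell back within the matched range and 4 passed a threshold. Cardiac transcription factors, sarcomere, calcium handling, chamber, endothelial and signalling genes stayed high in each. Housekeeping genes lost their place in 6. Germline genes were low within 10 kb (percentile 0.09) and over gene bodies (0.1), posterior Hox genes within 100 kb (2.0), and skeletal genes were high over gene bodies (97.9).

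Overlap of replicate 1 and of replicate 2 was 49.3% and 52.5% with 50% of both peaks shared, 60.5% and 70.8% with 50% of the peak asked about, and 64.0% and 73.1% by summit. At a -log10 q of at least 5 it was 66.0% and 86.6%, and in the 50000 strongest peaks 72.2% and 74.3%, where the other list is also shorter. The correlation was 0.654 with reciprocal overlap, 0.773 for -log10 p, 0.560 at the stricter q and 0.460 in the 50000 strongest. The last 2 settings leave out the weaker peaks. Of pooled peaks, 44.0% shared 50% of their length with each replicate, and 95.5% of those passing the stricter q were in the replicated list.

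Without either replicate, the share of summits within 1 kb of a TSS ranged from 8.16 to 8.57%, the centre over flank ratio at CpG-rich promoters from 0.230 to 0.231, the excess of long domains near heart genes from 6.71 to 7.01 times, the X ratio from 0.157 to 0.168 and the median heart motif ratio over reversed strings from 1.23 to 1.24. At the stricter q the first 4 were 10.6%, 0.197, 6.64 and 0.129, and with peaks found in both replicates all 5 were 10.1%, 0.203, 7.55, 0.138 and 1.23. The pooled list gave 7.92%, 0.235 and an X ratio of 0.185. All gene types gave 12.55%, since more TSSs count, and a centre over flank ratio of 0.241. Domain gaps of 0 and 3 kb and the widest gap gave 7.16, 6.48 and 3.16 times. By covered bp the X ratio was 0.109.

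The motif median was 1.28 within 100 bp, 1.18 over whole peaks, 1.18 with promoter peaks included and 1.15 in windows with few repeats. Of 162 ratios of single motifs in the alternatives, 126 moved beyond their spread, 29 did not and 7 changed side of 1, counting only motifs whose ratio in the report has intervals apart. These were the HAND and TWIST E-box within 100 bp (1.03), CTCF within 100 bp (0.433) and over whole peaks (0.743), SOX against flanking background (1.01), and SOX (1.03), POU (1.04) and CRX and OTX (1.01) in windows with few repeats, where the background loses its repeats. TBX, HNF4 and HNF1, whose intervals overlap in the report, crossed 1 in 8 further cases. Depth is not in the files, so weak peaks missing from a replicate cannot be read as absent.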

Other observations

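The gene families, the X genes named, the motif profile and the tests of chromosome X and of CTCF positions were chosen after the patterns were seen; of the tests, the one on heart motif positions was chosen after its result was seen.

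Gene families, grouped by the stem of their symbols, differed in H3K4me1 around their promoters. Of 141 families with at least 15 genes, 18 were high and 19 low among 2000 matched random lists. Inward rectifier potassium channels (Kcnj, 15 genes) had a median of 19.4% covered within 50 kb against a matched median of 5.23%. Semaphorins (Sema) had 18.6% against 10.7%, Wnt ligands 16.8% against 8.36%, Klf zinc finger factors 16.7% against 9.56% and Dusp phosphatases 15.8% against 9.31%. Stems that cover varied functions were high too, such as Lrrc (14.5% against 9.34%), Ankrd (14.7% against 9.70%), Tmem and Slc. The stems Ppp, Map, Rab, Cdc and Arhgef were also high. A function shared by the high families was not tested. Whether receptor and X genes lowered the matched medians was not tested. The beta protocadherins (Pcdhb), cell adhesion genes clustered on chromosome 18, had no covered bp in 21 of 22 genes, where matched lists had a median of 10.1%. Genes named Zfp, mostly zinc finger genes, had 5.13% over 394 genes against 9.48%, and cytochrome P450 genes (Cyp) 0.584% over 100 genes against 3.98%. Keratin associated (Krtap, 0.265% against 4.87%), Ugt, Sult, Lce and Sprr genes were low as well, each of the last 4 with a median of 0%, and so was the Rhox homeobox cluster on X, with 33 of 34 genes at 0%. The lists matched to Rhox were not limited to X, where genes had a median of 0.325% and those with CpG-poor promoters 0%, so the Rhox value is near that of X genes in general. Members of a clustered family share windows, so each such family counts as little more than 1 region.

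On chromosome X, the genes with the most H3K4me1 within 50 kb were Bcor, a corepressor gene (40.2%), Tbl1x, of the NCoR complex (23.2%), and Tsc22d3 (21.3%). The 8 listed genes on X had a median of 2.19%, against 13.5% for listed genes on autosomes.

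The low density of peaks on X, 0.159 of the autosomal median, was weighed against 3 technical explanations. Gene content is an unlikely whole cause, since X genes had a median covered percent 0.0606 times that of matched genes on the autosomes and Y. Repeat sequence left a ratio of 0.370 (95% bootstrap interval 0.329 to 0.412) in 100 kb windows of the same soft-masked share, up from 0.165 before weighting, so it may account for a part but not the whole. Fewer copies of X, with weak peaks missing the threshold, stays open: at CpG-rich promoters the median -log10 p of the strongest peak on X was 0.422 times that on autosomes (0.390 to 0.476), a value that lower marking of X would also give. No biological explanation was tested, since males and females were pooled and X inactivation cannot be set apart from copy number here.

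CTCF sites beside the summit, with a density ratio of 0.206, were weighed against base composition and a general property of binding sites. The reversed CTCF string had a ratio of 1.22 over only 13 and 16 matches. Its interval of 0.539 to 2.70 lies above 0.5, so this string showed no dip as deep as that of CTCF. So few matches cannot settle base composition in general, which stays open. The 10 heart motifs had a median of 1.13, so as a set their matches showed no such dip. MEF2 (0.517), SRF (0.914), NKX2 (0.946) and GATA (0.951) lay below 1 and the other heart motifs above it. This comparison was chosen after its result was seen, and a match need not be a bound site. It therefore cannot decide whether binding sites in general lie beside summits, which stays open. How the summit was placed within a peak is not given in the sources used here and stays open. No biological explanation was tested, since the data hold 1 group.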
